A study of Mus musculus with 27 samples.

How the data were processed

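RNA of the right lung of 11-week-old female mice was measured on 27 Mouse Gene 1.0 ST arrays, 3 mice for each of 9 inbred strains. The labels also give each strain a class of spontaneous pulmonary adenoma severity and frequency, increased or decreased. Per the labels' protocols, RNA was isolated with TRIzol, purified on RNeasy columns and checked on a Bioanalyzer, and biotin-labelled DNA was made with the WT cDNA synthesis kit. Per the submitters' processing notes the affy package was used, with its version not given. The normalization method is not given in the sources used here.

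The deposited table holds log2 signal of 21225 probe sets on each array. Values ran from 1.78 to 13.35 and the array medians from 6.24 to 6.37, so they were used as deposited, with no further scaling. The probe table gave a single gene symbol to 20239 probe sets and none to 986; no gene had more than 1 probe set, and the unnamed probe sets were left out of the tests. Gene order along the mouse assembly GRCm38.p6 was used only to find neighbouring genes. The number of arrays, 3 per strain, limits the precision.

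Computations used R 4.3.3 and limma 3.58.1. For the strains, lmFit was fitted to the 27 arrays with 1 mean per strain, followed by eBayes. A moderated F test asked whether a gene differed among the 9 strains. Each of the 36 strain pairs was a contrast, with the Benjamini-Hochberg adjustment within the pair; a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Genes called in at least 14 pairs, the number of pairs separated when 2 strains stand apart from 7, were termed common. Each strain was also compared with the mean of the other 8.

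For adenoma class the unit was the strain, because mice of a strain share genotype and class. The 3 arrays of a strain were averaged and lmFit and eBayes were applied to the 9 strain means. Severity increased (7 strains) was compared with decreased (2 strains), frequency increased (3 strains) with decreased (6 strains), and strains increased in both (3) with strains decreased in both (2). Calls were made at an adjusted p under 0.05, with no minimum difference, once over all named genes and once over the common genes.

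The analysis also used 44 gene lists, covering lung and immune cell types, other tissues and pathways; 750 of their 831 entries were on the array, 5 of them under an older symbol. Lists were tested with camera at its preset correlation of 0.01, which compares the genes of a list with all other genes, then with an estimated correlation, and with fry. The adjustment covered all lists of a comparison, and all strains and lists together for the strain contrasts.

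Genes were named by a fixed rule. It took the 20 genes called in the most pairs, and per strain the 2 genes higher and the 2 lower with the largest difference from the others. In each adenoma comparison it took up to 10 genes per direction among the calls, filled up by the smallest unadjusted p among genes with an absolute log2 difference of at least 0.5 and no overlap of the strain means. Up to 4 members of each list with the smallest p were eligible, and every lung tumour candidate. The gene lists, the tests of the report, the naming rule and the alternatives were fixed before the data were examined; the closing section names the tests chosen later.

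The fits were tested on simulated data of the same size. In the adenoma comparisons, with 200 genes changed by 1 on the log2 scale, 89%, 94.5% and 91.5% were recovered for severity, frequency and both, beside 14, 13 and 9 false calls. The strain F test recovered 191 of 200 changed genes with 8 false calls. A list shifted by 0.5 in a strain was recovered by camera with either correlation, with 1 other call at the preset and 0 with the estimated correlation. The simulated genes varied independently of each other. The list simulation therefore does not show how camera behaves with either correlation when genes are correlated.

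Alternatives covered quantile normalization, median centring, leaving out dim probe sets, all probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, and other minimum differences and minimum numbers of pairs. The adjustment was also made over all pairs together. Further alternatives took the strain as a random block, took the arrays as independent, and left out each array and each strain in turn. Array weights were not applied to the gene lists of the adenoma classes.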

Results

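Lung RNA was profiled in 3 female mice of each of 9 inbred strains, on 27 arrays. KK/HlJ and MRL/MpJ carry the label of decreased adenoma severity and frequency, and A/J, C57BL/6J and DBA/2J that of increased severity and frequency. In 129S1/SvlmJ, BALB/cJ, C3H/HeJ and C57L/J severity is labelled increased and frequency decreased. The run numbers in the array names followed the order of the strains, so run order and strain were not separable. The class is a property of the strain, not of the individual mouse, and the design states that 3 females per strain were taken, so replicates are separate mice. Arrays correlated at 0.984 to 0.997 within a strain and at 0.976 to 0.993 between strains, and 26 of the 27 were closest to an array of their own strain, the exception being C3H/HeJ replicate 3. Xist, transcribed from the inactive X chromosome of females, ranged from 10.01 to 10.60 across strain means, while the Y-linked genes, which have no template in females, read from 2.5 (Eif2s3y) to 5.25 (Sry). Levels in that range were not above background by this measure, and a difference from such a level is a lower bound. Above 3.56 the range rests on Sry alone, with strain means of 4.78 to 5.25. Nnt, part of which is deleted in C57BL/6J, was lowest there at 7.66 ± 0.13 (mean ± SD, n = 3) against 8.22 to 8.84 in the others. Gpnmb, which carries a stop mutation in DBA/2J, was lowest in that strain at 4.83 ± 0.21 against 6.32 to 8.30. Dysf, the dysferlin gene mutated in A/J, was lowest there at 5.39 ± 0.26 against 6.82 to 7.42. These are 3 of 12 listed genes known to vary between strains; 10 of the 12 passed the F test, and Mlph (adjusted p = 0.0803) and Disc1 (adjusted p = 0.318) did not. Klrd1, defective in DBA/2J, read 4.68 there and 4.28 in A/J, in the range of the Y-linked genes. In C3H/HeJ replicate 2 the median skeletal muscle gene was 4.68 and the median adipocyte gene 2.19 log2 above the mean of the other strains, against 0.15 and -0.11 in replicate 1 and 0.03 and 0.11 in replicate 3.

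Fbp2, the muscle isoform of fructose-1,6-bisphosphatase, separated the most strain pairs: it was called in 23 of 36, rising from 5.10 ± 0.17 in C57BL/6J to 8.38 ± 0.07 in KK/HlJ (n = 3 each, F adjusted p = 1.31e-15). Igha, the constant region of the IgA heavy chain, was called in 22 pairs, with 7.02 ± 0.11 in DBA/2J and 11.67 ± 0.74 in C57L/J (25.2-fold, adjusted p = 1.40e-08). H2-Q9, a non-classical MHC class I gene, was also called in 22 and ran from 4.56 ± 0.33 in MRL/MpJ to 8.35 ± 0.50 in KK/HlJ (adjusted p = 4.08e-11). Its neighbour in the family, H2-Q6, was called in 19, from 7.15 in MRL/MpJ to 9.89 in C57BL/6J. The chitinase-like gene Chil1 (21 pairs) was at 8.82 ± 0.05 in MRL/MpJ and 11.90 ± 0.06 in KK/HlJ (adjusted p = 1.32e-16). Spink5, a serine protease inhibitor, stood at 9.48 ± 0.09 in KK/HlJ and between 3.95 and 5.88 in the other 8 strains (20 pairs, adjusted p = 1.19e-16). H2-Ea, which encodes the alpha chain of the MHC class II molecule I-E, was called in 18 pairs (adjusted p = 2.55e-24). Its signal was at the level of the Y-linked genes in 3 strains, 4.79 ± 0.22 in C57BL/6J, 4.88 ± 0.32 in KK/HlJ and 4.90 ± 0.04 in 129S1/SvlmJ, and 10.92 to 11.42 in the other 6 strains, including 11.17 ± 0.09 in the arrays labelled C57L/J.

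Rps6, a protein of the small ribosomal subunit, was called in 21 pairs, with 6.98, 6.79 and 6.79 in C57BL/6J, KK/HlJ and MRL/MpJ and 3.08 to 4.71 in the other strains. Signal depends on the match of each strain's sequence to the probes as well as on transcript amount, which were not separated here. The pantetheinase gene Vnn3 was at 7.96 in DBA/2J and 4.79 in A/J, and Ccdc190 at 8.11 in A/J and 5.46 in DBA/2J, each in 20 pairs. Pcdhgb5, a gamma protocadherin, stood at 7.31 to 7.61 in 129S1/SvlmJ, C57BL/6J, KK/HlJ and MRL/MpJ and at 4.51 to 4.88 elsewhere. Ppbp, a platelet chemokine, ranged from 6.94 ± 0.87 in 129S1/SvlmJ to 10.89 ± 0.24 in KK/HlJ. Gatm, the first enzyme of creatine synthesis, was at 5.37 to 5.71 in KK/HlJ, C57BL/6J and MRL/MpJ and at 6.80 to 7.91 in the others. Krt79, a keratin, ranged from 6.47 ± 0.28 in BALB/cJ to 9.47 ± 0.13 in C3H/HeJ, and Mcoln3, a mucolipin channel, from 4.99 in DBA/2J to 7.78 in KK/HlJ (19 pairs each). The remaining genes of the 20 most often called were Abca17, Ly6d, Gm14548, 5830417I10Rik and Rpl31-ps21, called in 19 or 20 pairs.

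**Figure D1:**
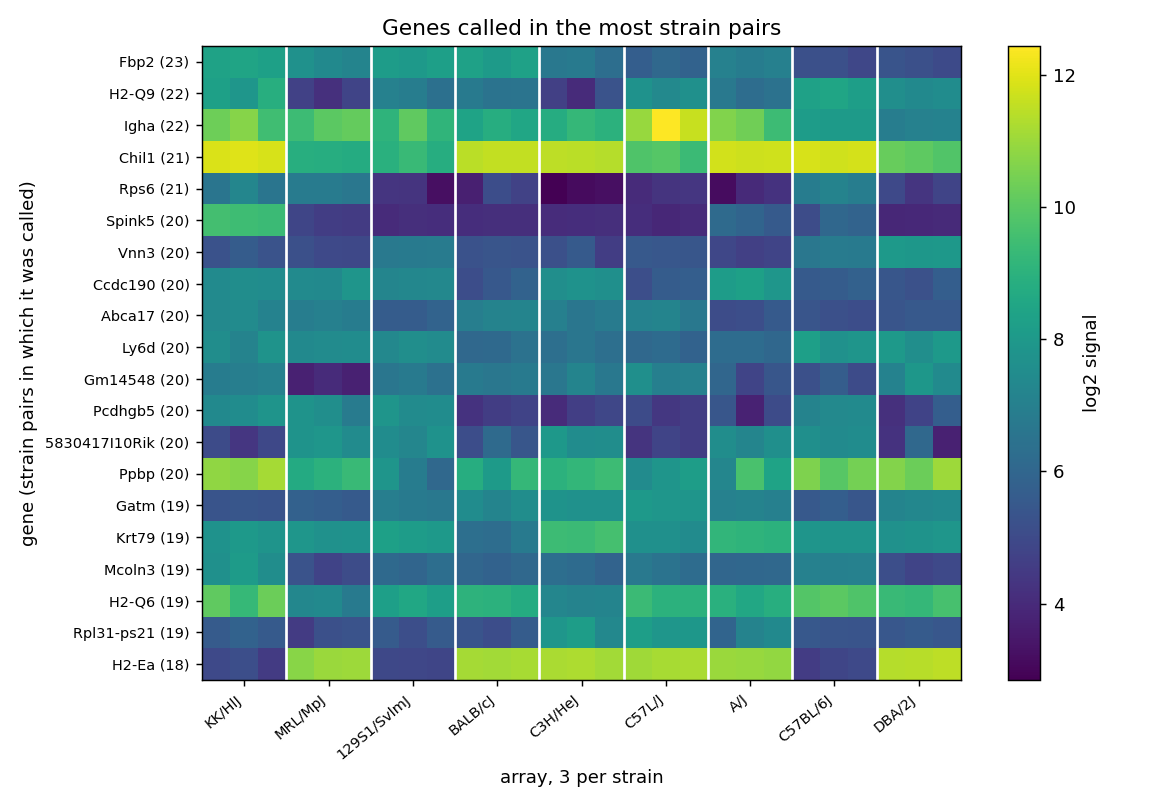
Log2 signal of the 20 genes called in the most strain pairs, on each of the 27 arrays, with 3 arrays per strain side by side. The number after each gene is the count of the 36 strain pairs in which it was called, from 23 for Fbp2 to 18 for H2-Ea.

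With the minimum log2 difference of 1, the most genes were called between C57L/J and KK/HlJ, 199 (92 higher and 107 lower in C57L/J), followed by C3H/HeJ and C57BL/6J with 182 (93 higher and 89 lower in C3H/HeJ). The fewest were called between A/J and BALB/cJ, 71 (34 higher and 37 lower in A/J), followed by C3H/HeJ and MRL/MpJ with 79. C57BL/6J and the arrays labelled C57L/J differed by 157 genes. The order depended on that minimum: without it the most calls were between C57BL/6J and MRL/MpJ (3341) and the fewest between C3H/HeJ and MRL/MpJ (834), while C57L/J and KK/HlJ had 1551 and A/J and BALB/cJ 936. The F test passed 5840 of 20239 genes; 864 were called in at least 1 pair, 268 in at least 8 and 83 in at least 14, and the median pair had 134 calls.

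**Figure D2:**
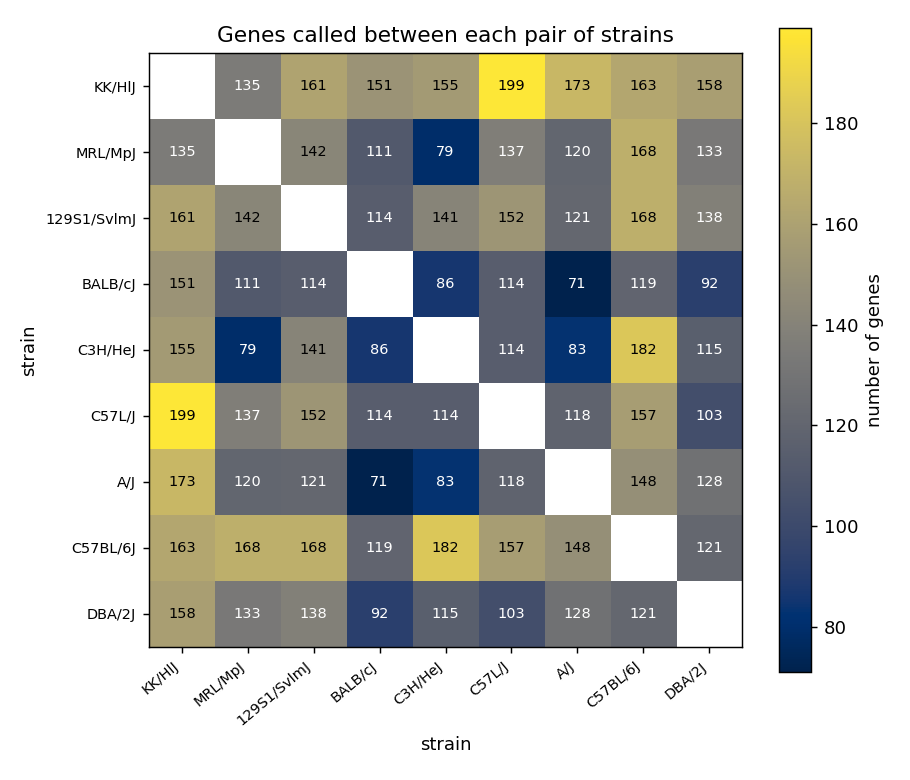
Number of genes called between each pair of the 9 strains (limma, adjusted p under 0.05 and an absolute log2 difference of at least 1; 3 mice per strain). Both axes list the strains, and counts ran from 71 to 199.

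Trim12a stood at 8.57 ± 0.25 in C57BL/6J and 8.17 ± 0.24 in KK/HlJ, 5.26 (SE 0.11, adjusted p = 5.14e-20) and 4.82 (SE 0.11, adjusted p = 2.50e-19) log2 above the mean of the other 8 strains. In C57BL/6J the histone gene H2az1 was also raised, by 3.92 (adjusted p = 2.61e-10), and the guanylate-binding protein gene Gbp2b fell by 2.73 (adjusted p = 4.57e-16). H2az1 was high in KK/HlJ too (8.45), and Gbp2b low in MRL/MpJ (4.43) and DBA/2J (4.76). DBA/2J was high in 6330403K07Rik (4.04, adjusted p = 1.45e-16) and in Stab2, a scavenger receptor of hyaluronan (3.57, adjusted p = 6.30e-20), each above all other strain means, and low in Gpnmb and Igha (-2.90 and -2.60). The arrays labelled C57L/J were high in Nell1 (3.10, adjusted p = 1.78e-14) and Igha (2.64) and low in Uevld (-4.08, adjusted p = 4.14e-12) and the lipid-transfer gene Stard10 (-4.00, adjusted p = 3.60e-21). Nell1 was high in KK/HlJ too (7.27 against 7.46 in C57L/J). Mamdc2 was at 4.11 ± 0.21 in MRL/MpJ against 8.60 to 9.14 in the others (-4.72, adjusted p = 5.41e-20). In MRL/MpJ Chchd2 fell by 2.87 (SE 0.56, adjusted p = 0.0014) with an SD of 2.13 among the 3 mice, and the IgG1 heavy chain gene Ighg1 rose by 2.23 (SE 0.54, adjusted p = 0.00872) with an SD of 1.35. The Chchd2 call was lost without replicate 3 (adjusted p = 0.0527), and the Ighg1 call without replicate 2 (adjusted p = 0.0777) or 3 (adjusted p = 0.0937).

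In A/J the interferon-inducible gene Ifi204 was 3.13 log2 higher (adjusted p = 3.18e-13), while H2-T22, a non-classical MHC class I gene, and Bst1, an ectoenzyme gene, were lower (-4.42 and -2.96, adjusted p = 1.35e-16 and 6.50e-18). H2-T22 was low in KK/HlJ as well (-3.85), and its level in both strains was in the range of the Y-linked genes. 129S1/SvlmJ was high in BC018473 (3.78) and Gdpd3, a lysophospholipase D gene (3.51, adjusted p = 6.15e-18). BC018473 was also high in KK/HlJ (8.37), and Gdpd3 in KK/HlJ (9.96) and C57L/J (9.40). 129S1/SvlmJ was low in Bpifa1, a secreted airway protein gene (6.84 ± 0.49 against 8.60 to 10.85, difference -3.17, adjusted p = 7.53e-08). BALB/cJ was high in Baiap2l1 (1.92, adjusted p = 3.27e-13) and low in Krt79 and Pcdhgb5 (-1.72 and -1.55). Its high Baiap2l1 level (10.42) was shared by A/J (10.44) and C3H/HeJ (9.99). Its low Pcdhgb5 level was shared by A/J, C3H/HeJ, C57L/J and DBA/2J (4.51 to 4.88). C3H/HeJ was high in the kallikrein gene Klk1b22 (3.58, adjusted p = 8.64e-12) and low in H2-Q9 (-2.36) and Serpina1b, an alpha-1-antitrypsin gene (-2.38; SE 0.56, adjusted p = 0.0104). Klk1b22 was at 7.33 in 129S1/SvlmJ and 7.44 in C3H/HeJ, and H2-Q9 at 4.56 in MRL/MpJ and 4.67 in C3H/HeJ. The lowest other strain mean of Serpina1b was 4.86, against 5.06 in C3H/HeJ. The Serpina1b call was lost without C3H/HeJ replicate 1 (adjusted p = 0.0757) or 2 (adjusted p = 0.0682) and with array weights (adjusted p = 0.123). H19, an imprinted non-coding RNA, was at 8.63 ± 1.35 in C3H/HeJ, 2.77 above the others (adjusted p = 1.44e-07), and 2.02 above without replicate 2. Over all genes, the strain calls ranged from 393 lower genes in DBA/2J to 1383 higher genes in MRL/MpJ.

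Alveolar macrophage markers set BALB/cJ apart. Of 13 measured, 9 fell and 0 rose (10 and 1 adjusted over the list alone), with Krt79 at -1.72, the scavenger receptor gene Marco at -1.05, Atp6v0d2 at -0.69 and the lipid transporter gene Abcg1 at -0.62, and a median of -0.50. The list was lower at an adjusted p of 1.91e-17, and 0.0246 with an estimated correlation. The same markers were higher in A/J (8 rose, 1 fell, the same counts adjusted over the list alone; median 0.29, adjusted p = 6.58e-09), where the adjusted p was 0.0954 with an estimated correlation. They were higher in C3H/HeJ (6 rose, 1 fell; 9 and 1 adjusted over the list alone; Pparg, also an adipocyte gene, 0.62, adjusted p = 1.37e-06, and adjusted p = 0.189 with an estimated correlation). Pparg was at 7.96, 8.28 and 7.73 in C3H/HeJ replicates 1, 2 and 3, and replicate 2 was the array with high adipocyte genes (2.19); without it the macrophage list had a median of 0.27 and an adjusted p of 7.30e-06. In KK/HlJ 6 rose and 0 fell (7 and 0 adjusted over the list alone), among them the chitinase-like gene Chil3 (1.78); the adjusted p was 5.32e-06, and 0.197 with an estimated correlation. In MRL/MpJ Chil3 and Fabp1 were lower (-1.08 and -1.45). The list was called lower in MRL/MpJ, DBA/2J and C57L/J too (medians -0.14, -0.15 and -0.07), with adjusted p = 0.405, 0.405 and 0.528 with an estimated correlation. The call in MRL/MpJ was lost with dim probe sets left out (adjusted p = 0.0608) and that in C57L/J without its replicate 3 (adjusted p = 0.108) or KK/HlJ replicate 3 (adjusted p = 0.0568).

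NK cell and cytotoxic markers were low in A/J and 129S1/SvlmJ. Of 15 measured, 9 fell in A/J (13 adjusted over the list alone), led by the granzyme gene Gzma (-1.81) and the NK receptor gene Ncr1 (-0.97), with a median of -0.50; the adjusted p was 1.56e-12, and adjusted p = 0.147 with an estimated correlation. In 129S1/SvlmJ 10 fell (14 adjusted over the list alone; Ncr1 -1.04, Nkg7 -0.85, adjusted p = 1.08e-09, and adjusted p = 0.197 with an estimated correlation). In C57BL/6J 4 rose (9 adjusted over the list alone), Klra8 by 2.66 and Klrb1c by 0.87 (adjusted p = 6.50e-08, and adjusted p = 0.229 with an estimated correlation). B cell markers were low in 129S1/SvlmJ, where 7 of 14 fell (13 adjusted over the list alone), with Fcer2a, the low-affinity IgE receptor gene, at -0.97 (adjusted p = 4.61e-06, and adjusted p = 0.430 with an estimated correlation). In MRL/MpJ 3 of them fell (5 adjusted over the list alone; Fcer2a -0.74, Ighd -0.95, adjusted p = 1.66e-05, and adjusted p = 0.430 with an estimated correlation). Dendritic cell genes were low in 129S1/SvlmJ, with Cd209a at -1.81 and Clec9a at -1.28 and 6 of 12 falling (7 adjusted over the list alone, adjusted p = 2.70e-05, and adjusted p = 0.0503 with an estimated correlation).

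Cell cycle genes were high in C57BL/6J. Of 31 measured 16 rose and 0 fell (17 and 0 adjusted over the list alone), with the helicase subunit gene Mcm6 at 0.92, Bub1b at 0.79 and Top2a at 0.77 (adjusted p = 1.25e-18, and adjusted p = 0.0503 with an estimated correlation). In 129S1/SvlmJ 8 fell (14 adjusted over the list alone), Mcm6 (-0.86) and Top2a (-0.81) among them (adjusted p = 1.03e-05, adjusted p = 0.126 with dim probe sets left out, and adjusted p = 0.341 with an estimated correlation). The interferon-inducible GTPase genes Iigp1 and Igtp differed by 0.96 and 0.79 in C57BL/6J and by -1.08 and -0.96 in 129S1/SvlmJ. Of 31 interferon-stimulated genes, 9 rose in C57BL/6J (12 adjusted over the list alone, adjusted p = 6.50e-08, and adjusted p = 0.405 with an estimated correlation). In 129S1/SvlmJ 10 fell and 1 rose (16 and 2 adjusted over the list alone, adjusted p = 2.48e-04, adjusted p = 0.122 with dim probe sets left out, and adjusted p = 0.528 with an estimated correlation). In A/J 10 fell and 1, Ifi204, rose (14 and 1 adjusted over the list alone, adjusted p = 4.16e-07, and adjusted p = 0.407 with an estimated correlation).

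Ciliated cell markers were low in 129S1/SvlmJ and BALB/cJ. Of 15 measured 10 fell in 129S1/SvlmJ (12 fell and 1 rose adjusted over the list alone), with the radial spoke gene Rsph1 at -0.86 and the dynein heavy chain gene Dnah5 at -0.58 (adjusted p = 6.50e-08, and adjusted p = 0.229 with an estimated correlation). In BALB/cJ 7 fell (9 adjusted over the list alone, adjusted p = 1.67e-08, and adjusted p = 0.197 with an estimated correlation). In A/J the mucin gene Muc5b rose by 1.19, Bpifb1 by 1.35 and the antimicrobial lectin gene Reg3g by 1.68; 3 of 9 goblet and mucus genes rose (6 adjusted over the list alone, adjusted p = 3.74e-07, and adjusted p = 0.189 with an estimated correlation). Aldh3a1, an aldehyde dehydrogenase gene, was 0.86 higher in A/J, and 9 of 35 xenobiotic metabolism genes rose there while 1 fell (14 and 2 adjusted over the list alone, adjusted p = 5.49e-10, and adjusted p = 0.0741 with an estimated correlation). Among alveolar type II cell markers, the complement gene Hc and the surfactant gene Sftpd were 1.17 and 0.38 higher in C57BL/6J, where 6 of 15 rose (8 adjusted over the list alone, adjusted p = 7.79e-08, and adjusted p = 0.304 with an estimated correlation).

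Skeletal muscle genes were high in C3H/HeJ, where Myl1 was 2.14 and the actin gene Acta1 1.91 above the other strains; 7 of 12 rose (12 adjusted over the list alone, adjusted p = 8.31e-07, and adjusted p = 0.430 with an estimated correlation). Without replicate 2 their median went from 1.58 to 0.09, with an adjusted p of 0.289. Adipocyte genes of C3H/HeJ had a median of 0.79, with 0 of 12 passing over all genes or adjusted over the list alone (adjusted p = 0.00254, and adjusted p = 0.643 with an estimated correlation); without replicate 2 the median was -0.02. Cardiac genes, present in lung in the muscle sleeve of the pulmonary veins, were high in MRL/MpJ, with Actc1 at 0.91 and Tnni3 at 0.83 and a median of 0.61 (11 of 15 rose, the same count adjusted over the list alone, adjusted p = 2.46e-06, and adjusted p = 0.405 with an estimated correlation). They were low in BALB/cJ, with Actc1 at -0.99 and Pln, the phospholamban gene, at -0.86 (8 fell and 1 rose of 15; 10 and 1 adjusted over the list alone, adjusted p = 1.81e-06, and adjusted p = 0.405 with an estimated correlation).

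Clock genes differed in DBA/2J, where the period genes Per1 and Per3 were lower (-0.61 and -0.53) and Npas2 higher (0.51); 8 of 17 fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 4.00e-04, and adjusted p = 0.229 with an estimated correlation). In MRL/MpJ the cholesterol synthesis genes Fdft1 and Lss were at -0.34 and -0.33, with 7 of 19 lipid synthesis genes lower, the same count adjusted over the list alone (adjusted p = 7.31e-05, and adjusted p = 0.197 with an estimated correlation). In C57L/J Igha and Jchain, the joining chain of IgA and IgM, led the plasma cell genes at 2.64 and 2.37, with 2 of 11 rising (4 adjusted over the list alone, adjusted p = 0.0164, and adjusted p = 0.405 with an estimated correlation). With dim probe sets left out the plasma cell median was -0.02 (adjusted p = 0.509), and without C57L/J replicate 2 the adjusted p was 0.202. Over 396 strain and list combinations camera called 126 at its preset correlation, and with an estimated correlation only the alveolar macrophage list of BALB/cJ remained. fry, which tests whether the genes of a list move on balance in a single direction without comparing them with other genes, called 104. In 3 of the 126 the signs differed: clock genes in A/J (median -0.0008, mean 0.09, test higher), MHC class II genes in C57BL/6J (median 0.31, mean -0.06, test higher) and MHC class I genes in KK/HlJ (median 0.16, mean -0.05, test higher).

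**Figure D3:**
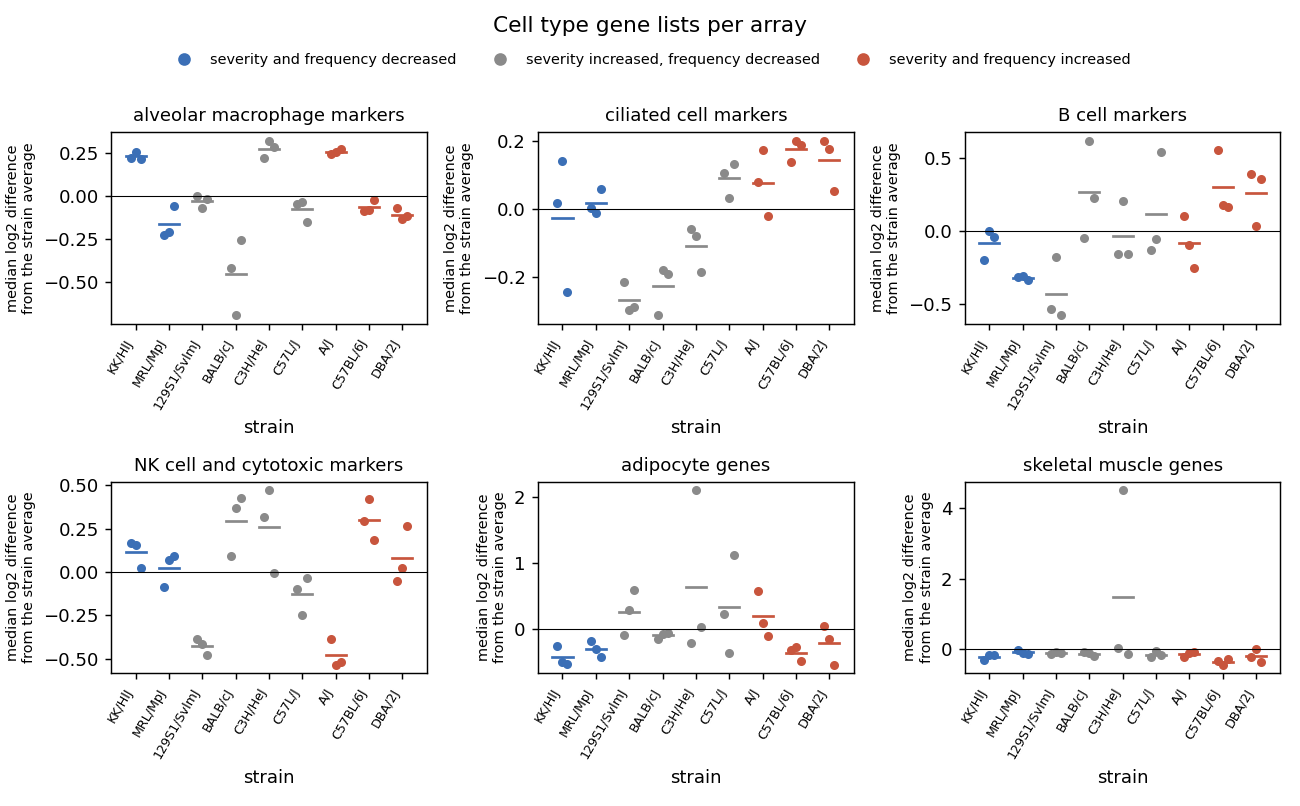
Median log2 difference of the genes of 6 lists from the average of the 9 strains; each point is an array, lines are means of 3 arrays, and colour gives the adenoma class. C3H/HeJ replicate 2 was the highest array for the adipocyte and skeletal muscle genes.

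B4galnt2, which encodes a glycosyltransferase, and the predicted gene Gm7582 were lower in the 7 strains with increased adenoma severity. B4galnt2 was at 4.02 ± 0.09 there (SD over strain means) against 5.002 ± 0.0065 in KK/HlJ and MRL/MpJ, a difference of -0.98 (SE 0.07, adjusted p = 0.00206). Gm7582 was at 6.55 ± 0.16 against 7.87 ± 0.25 (-1.32; SE 0.13, adjusted p = 0.0117), a call lost without 129S1/SvlmJ replicate 2 (adjusted p = 0.0694) or C57BL/6J replicate 3 (adjusted p = 0.0736). For both genes all 7 strain means lay below those of KK/HlJ and MRL/MpJ. The levels of B4galnt2 in both classes lay within the range of the Y-linked genes, so its difference stands on signal not shown to be above background. With dim probe sets left out B4galnt2 was not tested, and Gm7582 was the 1 severity call left. Hepacam, a cell adhesion gene, was at 5.28 ± 0.16 against 7.99 in KK/HlJ and 6.72 in MRL/MpJ (-2.08, SE 0.25). It passed among the 83 common genes (adjusted p = 7.39e-04) but not over all genes (adjusted p = 0.0601). The common genes were picked for large strain differences, and 18 of 36 splits of the strains gave at least 1 call among them. Lower without passing, and with no overlap of the strain means, were Igkv5-45 (-0.54), Trav13-3 (-0.58), the signalling co-receptor gene Tdgf1 (-0.70), Raet1d (-0.64), the sodium channel gene Scn3b (-1.13), Gap43 (-0.56) and the apolipoprotein gene Apoc1 (-0.68); Igkv5-45 and Raet1d lay in the range of the Y-linked genes in both classes. Higher without passing were Capg, an actin-capping protein gene (7.92 ± 0.08 against 6.82 ± 0.64; 1.09, adjusted p = 0.230), the stromelysin gene Mmp3 (1.32, adjusted p = 0.521), Retnla (1.14) and the immunoglobulin light chain genes Igkv4-57 (1.05) and Iglc2 (0.75). The same held for Zfp931 (1.37), Fsd1l (0.87), Ccdc163 (0.82), Txndc16 (0.54) and Gm5921 (0.53), with Zfp931 in the range of the Y-linked genes in both classes. The comparison gave 2 calls, both lower, and 1425 genes had an unadjusted p under 0.05. With only 2 strains in the decreased class, 6.69% of all genes showed no overlap of the strain means, where chance gives 5.56%.

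No gene passed over all genes for adenoma frequency. Abca17, an ABC transporter gene, was the single gene passing among the common genes: it was at 5.26, 5.23 and 5.48 in A/J, C57BL/6J and DBA/2J and at 6.83 to 7.31 in the decreased strains except 129S1/SvlmJ with 5.72 (-1.49; SE 0.29, adjusted p = 0.0338 among the common genes, 0.647 over all genes). This call was lost when any of 8 of the strains was left out (adjusted p = 0.0647 to 0.201), without 129S1/SvlmJ replicate 3 (adjusted p = 0.0516), with quantile normalization (adjusted p = 0.0520) and with the trended robust prior (adjusted p = 0.0641). Without 129S1/SvlmJ, the decreased strain with the low level, Abca17 passed over all genes (-1.70, adjusted p = 0.00176). Leaving out the strain that went against the split favours such a call, so this adds no evidence. Aldh3a1 was at 7.65 ± 0.21 in the 3 strains with increased frequency and 6.84 ± 0.30 in the other 6, a difference of 0.81 (SE 0.17, adjusted p = 0.647), with no overlap. Also higher without passing were the cilia genes Armc3 (0.66) and Cfap161 (0.54), the disulfide isomerase gene Agr3 (0.54), Itprid1 (0.58), Sh2d1b1, an adaptor of NK cells (0.84), Gm8730 (0.53), Gm6252 (0.77) and Mir680-1 (0.58). Agr3 lay in the range of the Y-linked genes in all strains but C57BL/6J (5.39). Dysf (-0.82), Bst1 (-1.18) and the contactin gene Cntn1 (-0.96) were lower without passing; Dysf and Bst1 were at 5.39 and 4.53 in A/J, and the lowest of the other strain means were 6.82 and 7.23. limma gave 0 calls over all genes (lowest adjusted p 0.647) and 1558 genes at an unadjusted p under 0.05; on the 27 arrays it gave 16 with the strain as a random block and 157 with the arrays taken as independent. Strain means did not overlap in 3.92% of genes, against 2.38% by chance.

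Between the 3 strains increased in both traits and the 2 decreased in both, B4galnt2 was again lower, at 3.97 ± 0.10 against 5.002 ± 0.0065 (-1.03; SE 0.08, adjusted p = 0.0096), again in the range of the Y-linked genes, and with dim probe sets left out there were 0 calls. All of these strains were also in the severity comparison, in the same direction, so this is not an independent finding. Hepacam (-1.99, adjusted p = 0.00717 among the common genes, 0.404 over all) and Abca17 (-1.80, adjusted p = 0.0264 among the common genes, 0.404 over all) were lower among the common genes only. Abca17 lost this call without A/J (adjusted p = 0.0678) or DBA/2J (adjusted p = 0.0671). It passed over all genes without 129S1/SvlmJ (adjusted p = 0.00934), whose low level stood apart from the rest of its class and widened the spread. Its difference was -1.61 without KK/HlJ and -1.98 without MRL/MpJ, each leaving 1 strain in the decreased class. Gm7582 (-1.22) and the T cell receptor gene Trav13-3 (-0.70) stood at an adjusted p of 0.0609. Lower without passing were Igkv4-62 (-1.13), Trav13d-4 (-0.58), Prr23a1 (-0.51), Igkv5-45 (-0.52) and Gucy1a2, a subunit of soluble guanylate cyclase (-0.52). Higher without passing were the tetraspanin gene Tspan1 (9.03 ± 0.08 against 8.46 ± 0.16; 0.57, adjusted p = 0.404), Cd55, a complement inhibitor (0.55), Aldh3a1 (1.04), Capg (1.15), Fsd1l (1.00), Gm8730 (0.72), Ublcp1 (0.71), Olfr1333 (0.79), Igkv4-57 (0.98) and Igkv6-17 (0.93). Igkv4-62, Igkv5-45 and Igkv6-17 lay in the range of the Y-linked genes in both classes. The comparison gave 1 call, B4galnt2, with 1745 genes at an unadjusted p under 0.05, and 27.05% of genes showed no overlap of the strain means, against 20% by chance.

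**Figure D4:**
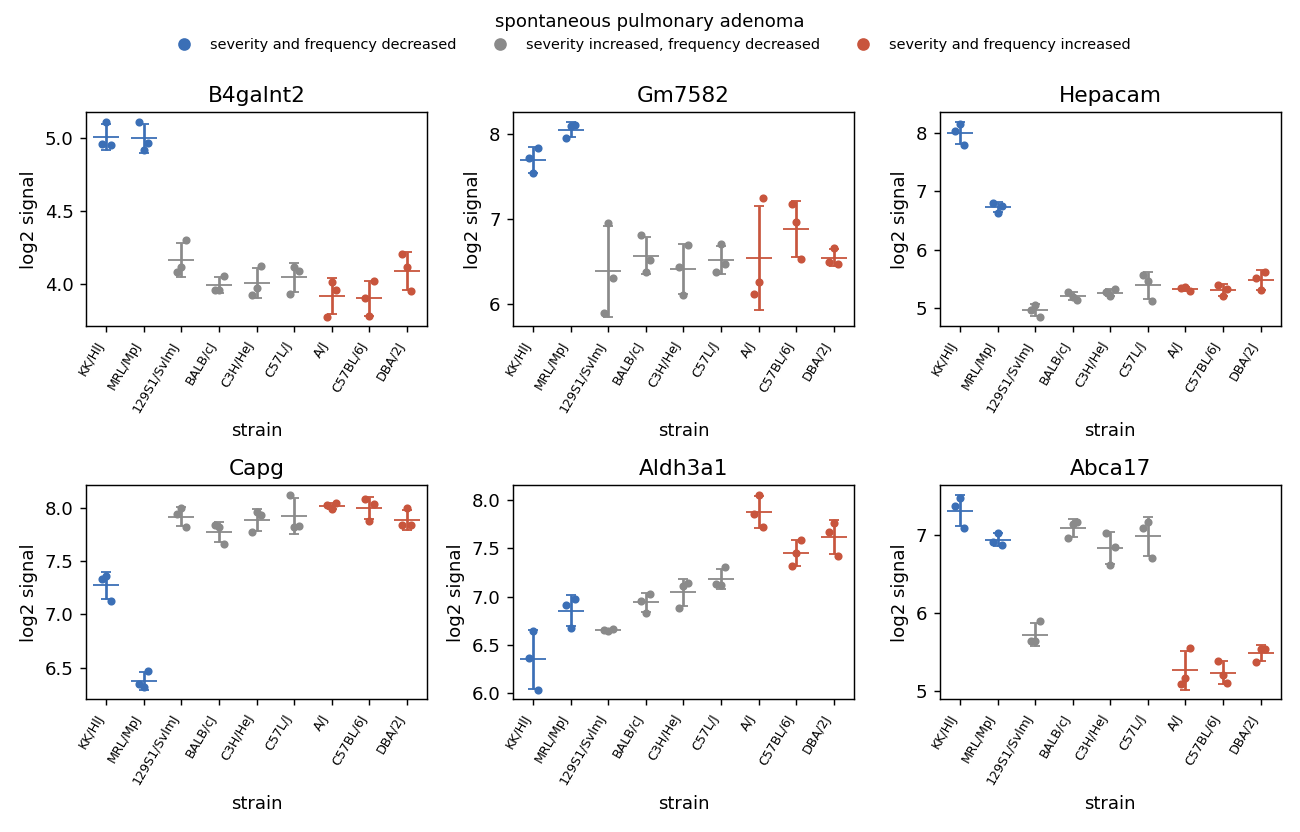
Log2 signal of 6 genes in the 9 strains, coloured by adenoma class; points are mice, horizontal marks means and bars SD (n = 3). B4galnt2 was near 5.0 in KK/HlJ and MRL/MpJ and at 3.91 to 4.17 elsewhere.

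Among 19 measured candidate genes of lung tumour susceptibility, none passed over all genes in any of the adenoma comparisons. Adjusted over the list alone, Aldh3a1 passed for frequency (0.81, adjusted p = 0.0134) and for both traits (1.04, adjusted p = 0.00764), and not for severity (0.65, adjusted p = 0.221). Casc1, a candidate of the Pas1 region, differed by -0.09 for severity, 0.09 for frequency and -0.01 for both, and the telomerase gene Tert by -0.17, -0.16 and -0.24. Tert, Bcat1, Rgs17, Chrna3, Chrna5 and Chrnb4 lay in the range of the Y-linked genes in all strains, so their differences are not shown to be above background.

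B cell markers were higher in the classes with increased adenomas, without any single gene passing. For severity 13 of 14 were positive, with Ighm at 0.62, Ighd at 0.66 and a median of 0.28 (adjusted p = 1.13e-05, and adjusted p = 0.755 with an estimated correlation). Without MRL/MpJ the median was 0.12 and the adjusted p 0.120. For frequency all 14 were positive (median 0.23, adjusted p = 1.68e-07, and adjusted p = 0.486 with an estimated correlation), and for both traits as well, with Ighd at 0.90 and a median of 0.39 (adjusted p = 5.44e-08, and adjusted p = 0.535 with an estimated correlation). Adipocyte genes were higher with severity in 11 of 12, with the adipokine gene Adipoq at 1.10 and the fatty acid binding gene Fabp4 at 1.11 and a median of 0.53 (adjusted p = 2.21e-06, and adjusted p = 0.755 with an estimated correlation); without C3H/HeJ replicate 2 the median was 0.41. For frequency 11 of the 12 were negative (median -0.18, adjusted p = 0.525), and for both traits 10 were positive (median 0.21, adjusted p = 0.00223, and adjusted p = 0.839 with an estimated correlation). Ciliated cell markers were higher with frequency in 13 of 15, with Dnah5 at 0.43 and Ccdc113 at 0.33 and a median of 0.21 (3 adjusted over the list alone, adjusted p = 7.23e-10, and adjusted p = 0.486 with an estimated correlation). The xenobiotic genes led by Aldh3a1 were higher with frequency in 26 of 35 (1 adjusted over the list alone, adjusted p = 1.68e-07, and adjusted p = 0.199 with an estimated correlation). Club cell markers were higher with frequency in 9 of 9, with the secretoglobin gene Scgb3a1 at 0.77 (adjusted p = 5.48e-05, and adjusted p = 0.199 with an estimated correlation).

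Adjusted over the list alone, 0 B cell or adipocyte genes passed in any adenoma comparison, and 0 club cell markers passed for frequency. Mitochondrial respiratory chain genes had a median of 0.06 with severity (20 of 27 positive, adjusted p = 1.37e-04, and adjusted p = 0.799 with an estimated correlation); they were 0.58 above the other strains in C3H/HeJ replicate 2. Without MRL/MpJ their median was 0.03 and the adjusted p 0.318. The complement genes C1qb and C1qc, at 0.37 and 0.36, passed adjusted over the list alone for severity (median 0.05, adjusted p = 0.0155, and adjusted p = 0.755 with an estimated correlation). Ribosomal protein genes differed in sign for severity, with a median of 0.08, a mean of -0.02 that included Rps6 at -2.33, and a test for higher values (adjusted p = 0.00504, and adjusted p = 0.755 with an estimated correlation). camera called 10, 12 and 14 lists for severity, frequency and both at its preset correlation, all higher in the increased class, and 0 in each with an estimated correlation (lowest adjusted p 0.755, 0.199 and 0.509). The median difference over all genes was -0.027, -0.036 and -0.046. As camera compares a list with all other genes, a list can be called higher partly because the other genes were slightly lower. fry called 0 lists in each comparison (lowest adjusted p 0.971, 0.377 and 0.736).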

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

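The tests of carry-over and of a strain difference in C3H/HeJ, both tests of the C57L/J arrays, the test of the higher side in C57BL/6J and the repeats without C3H/HeJ replicate 2 are tests chosen only after the results were seen.

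In 4 of 33 groups of strain means a strain lay far from the others, its gap to the nearest divided by the range being above Dixon's limit; chance flags about 1 in 20 groups. Gm7582 in the severity-increased class was 6.88 in C57BL/6J and 6.38 to 6.57 in the other 6 strains of that class (gap over range 0.635). Abca17 in the frequency-decreased class was 5.72 in 129S1/SvlmJ against 6.83 to 7.31 (0.697), and Cntn1 in the same class was 7.87 in 129S1/SvlmJ against 5.47 to 6.24 (0.682). Dysf in that class was 7.42 in MRL/MpJ against 7.10 to 7.21 (0.640). Outside the tests of the report, 262 of the 986 probe sets without a gene symbol differed among the strains, 26.6% against 28.7% of the named ones; they were set aside only for lack of a name.

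C3H/HeJ replicate 2 carried the transcripts of muscle and fat: Acta1 was 11.56 against 6.22 in the other strains, Myh1 10.17 against 3.83 and Ucp1, the thermogenic protein of brown fat, 9.85 against 5.01. All 12 skeletal muscle genes and 10 of 12 adipocyte genes were at least 1 log2 above the other strains. The median muscle gene of replicates 1 and 3 was 0.0914 above the other 24 arrays and 1 of the 3 arrays was raised, which is in line with tissue carried over into that sample and excludes a difference of the whole strain. At 97% of 100 genes with 2 expression levels, replicate 2 was on the side of the other C3H/HeJ mice, which goes with its label. At the 36 such genes shared by several strains, A/J and BALB/cJ had the level of C3H/HeJ in 86.1% and 83.3%. The 97% therefore cannot exclude a mislabelled mouse of a strain with similar levels. The muscle and fat lists of C3H/HeJ rest on replicate 2 and say nothing about the lung of the strain.

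The values of the arrays labelled C57L/J do not settle their relation to C57BL/6J. At 36 genes with 2 levels shared by several strains they had the level of C57BL/6J in 33.3%, the lowest of the 8 strains and at -16.7 percentage points from the median of the others (95% bootstrap interval -33.3 to -2.78), and over all 113 such genes in 56.6%, beside 57.5% in C3H/HeJ and 73.5% in BALB/cJ. The 1160 calls between them with no minimum difference were the next to fewest of the 8 pairs of C57BL/6J (961 with DBA/2J, 3341 with MRL/MpJ). With the minimum of 1 their 157 calls were mid-range (119 with BALB/cJ to 182 with C3H/HeJ). KK/HlJ, C57BL/6J, C57L/J and DBA/2J came first in the order of the samples, and run order was not separable from strain. The counts with no minimum could therefore follow run order and cannot decide the label. A mislabelled strain could give the low shares and the H2-Ea signal of 11.17, a gene not transcribed in the H2b haplotype listed for C57L/J. A correctly labelled strain that differs from C57BL/6J at these few genes could give the low shares. It could give the H2-Ea signal only if the listed haplotype were wrong. A swap with KK/HlJ stays open. Low H2-Ea (4.88) and high Trim12a and H2az1 in KK/HlJ go with it, while the 63.7% shared over all 113 genes and the 163 calls go against it. With no minimum, C57BL/6J and KK/HlJ had 1319 calls, between 1160 with C57L/J and 1329 with A/J. Setting C57BL/6J and KK/HlJ against the rest gave 13 calls, the most of the 36 severity splits. As these strains came first in the order of the samples, run order could give this too. At the 36 genes KK/HlJ, with 61.1%, was 2.78 percentage points above the next strain (95% bootstrap interval -25 to 22.2, 2000 draws). Both intervals take the 36 genes as independent. Trim12a with Trim34b and H2-T22 with H2-T23 were neighbours with the same split, so both intervals are likely too narrow.

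Genes with 2 levels, such as Trim12a and H2az1, often had C57BL/6J on the higher side. This held at 50.4% of 113 genes, where 40.1% would follow from the sizes of the groups (permutation p = 0.0024, 10000 permutations); the next strain, C3H/HeJ, had 48.7%. Strain variants under probes designed on the C57BL/6J reference could lower the signal of the other strains in this way, and without C3H/HeJ replicate 2 the shares were 53% and 49% for the next, KK/HlJ (permutation p = 0.0041). Predicted genes and pseudogenes made up 2.65% of the genes with 2 levels and 2.97% of the others (exact p = 1), which leaves signal shared between near-identical copies open, as gene names miss many such copies. A regulatory difference at the gene gives the same picture, and probe sequences were not used here. The permutations took genes as independent, although some neighbouring genes shared their split, so the permutation p of each is likely too small.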

How the results depend on the processing

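None of the tests in this part was chosen only after a result was seen. The 5840 genes of the F test ranged from 4620 with dim probe sets left out to 6860 with array weights, and the number of pairs of each named common gene stayed within the same range in all 152 values under other settings and all 540 without an array. Of 407 values of the named strain lists under other settings, 365 kept direction and call; the 156 values of the named adenoma lists kept theirs in 124. The camera calls at the preset correlation were the main casualty: with an estimated correlation they fell from 126 to 1 for strains, and from 10, 12 and 14 to 0, 0 and 0 for severity, frequency and both, and fry gave 0, 0 and 0. Signal over background limits what dim genes can show, and leaving out the dimmer probe sets was the measure of it here. Run numbers in the array names followed the order of the strains, so run order and strain cannot be separated. Keeping genes with a single symbol and the mean over probe sets could not differ, since each gene had a single probe set and symbol, and an alternative for values not on a log scale did not apply.

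With no minimum difference the median pair had 1345 calls and 978 genes were common; with a 1.5-fold minimum these were 472.5 and 314, by construction. Common genes numbered 268 at 8 or more pairs and 32 at 18 or more; severity calls among them were then 2 at 8 or more, frequency calls 0, and calls for both 1 at 18 or more. With dim probe sets left out, the median pair was 75.5 and the common genes 51, since fewer genes were tested; severity had 1 call, Gm7582, and 0 common calls, frequency 0 common calls and 5 lists, and both 0 calls, 0 common calls and 9 lists. B4galnt2, Hepacam and Abca17 are among the dim genes and were then not tested. For strain lists the same omission ended the calls of cell cycle genes (adjusted p = 0.126) and interferon-stimulated genes (0.122) in 129S1/SvlmJ, of plasma cell markers in C57L/J (0.509), of alveolar macrophage markers in MRL/MpJ (0.0608) and of adipocyte genes in C3H/HeJ (0.0641). Quantile normalization gave frequency 0 common calls and 7 lists and both 8 lists, median centring gave severity 5 lists, and the trended robust prior gave frequency 0 common calls; the cause was not tested. Taking arrays rather than strain means as the unit raised the counts by construction: with the strain as a random block severity had 73 calls (14 common), frequency 16 (2) and both 56 (18), and with independent arrays 323 (14), 157 (2) and 476 (19).

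The replicate number as a block, with the strain as a random block, gave 61 severity calls (13 common), 6 for frequency (2) and 32 for both (12). The random block alone gave the counts above. A check of the pairing found a mean correlation of 8.67e-05 among 108 same-numbered pairs of arrays after removing strain means (-0.272 to 0.276), so the numbers do not appear to link mice.

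Leaving out each array, then each strain, gave these ranges. F test 5181 to 6103; median pair 129 to 142.5; common genes 80 to 85; strain lists 119 to 132. Severity: calls 1 to 3, then 2 to 53; common calls 1 to 2, then 1 to 5; lists 5 to 12, then 6 to 14. Frequency: calls 0 to 0, then 0 to 1; common calls 0 to 1, then 0 to 1; lists 12 to 15, then 8 to 16. Both: calls 1 to 2, then 1 to 38; common calls 2 to 2, then 1 to 6; lists 11 to 16, then 9 to 15. The highest severity count came without MRL/MpJ, which leaves KK/HlJ alone in its class and assumed to vary like the others. The adipocyte list of C3H/HeJ reversed to -0.0216 without C3H/HeJ replicate 2 and reached 1.27 without replicate 1, since replicate 2 carried that signal. Gm7582 lost its severity call without 129S1/SvlmJ replicate 2 (adjusted p = 0.0694) or C57BL/6J replicate 3 (0.0736), and Abca17 its common call for frequency without 129S1/SvlmJ replicate 3 (0.0516), with quantile normalization (0.0520), with the trended robust prior (0.0641) and without any of 8 strains (0.0647 to 0.201). For both traits Abca17 lost its common call without A/J (0.0678) or DBA/2J (0.0671). Its difference was -1.61 without KK/HlJ and -1.98 without MRL/MpJ, each leaving 1 strain in the decreased class. Without 129S1/SvlmJ Abca17 passed over all genes for frequency (-1.70, adjusted p = 0.00176) and for both traits (-1.80, adjusted p = 0.00934). That strain had the outlying low level of its class, so leaving it out favours the call and adds no evidence. Without MRL/MpJ the severity lists of B cell markers (median 0.12, adjusted p = 0.120) and mitochondrial genes (0.03, adjusted p = 0.318) lost their calls. Hepacam passed over all genes for severity without DBA/2J replicate 3 (0.0484), KK/HlJ replicate 2 (0.0440) or MRL/MpJ replicate 2 (0.0397). For both traits Gm7582 passed without C57BL/6J replicate 1 (0.0166) or KK/HlJ replicate 2 (0.0351), and Trav13-3 without KK/HlJ replicate 3 (0.0103). Calls were also lost for Serpina1b without C3H/HeJ replicate 1 (0.0757) or 2 (0.0682) or with array weights (0.123), for Chchd2 without MRL/MpJ replicate 3 (0.0527), and for Ighg1 without MRL/MpJ replicate 2 (0.0777) or 3 (0.0937). The skeletal muscle list of C3H/HeJ was lost without its replicate 2 (0.289), the goblet list of 129S1/SvlmJ without its replicate 1 (0.0979) and the plasma cell list of C57L/J without its replicate 2 (0.202). Alveolar macrophage markers of C57L/J lost their call without C57L/J replicate 3 (0.108) or KK/HlJ replicate 3 (0.0568). The cause was not tested.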

Other observations

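The overlap of the common genes with the gene lists is the set of tests here chosen only after the results were seen; the neighbour test and the splits were written before.

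MHC class I genes had the lowest p among the lists tested for overlap with the 83 common genes. Of 19 MHC class I genes, H2-Q6, H2-D1, H2-T22 and H2-T23 were common (exact test over 44 lists, adjusted p = 4.28e-05). The exact test counts genes as independent, but H2-T22 and H2-T23 were direct neighbours with the identical split, so this p overstates the evidence. Whether common members of the other lists are linked was not examined. Of 13 alveolar macrophage markers 3 were common, the chitinase-like gene Chil3, Marco and Krt79 (exact, adjusted p = 2.71e-04), and of 9 goblet and mucus genes the secreted airway genes Bpifa1 and Bpifb1 (exact, adjusted p = 0.00646). Gzma and the NK receptor gene Klra8 were common among 15 cytotoxic genes (exact, adjusted p = 0.0148), and H2-Ea, Trim12a and Gpnmb among 12 genes known to vary between strains (exact, adjusted p = 2.71e-04). Trim30d and Ifi211 were the common interferon-stimulated genes (exact, adjusted p = 0.0525).

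Neighbouring genes split the strains alike more often than in random placements. Of 113 genes with 2 levels, 51 were high in a single strain, 26 low in a single strain and 36 shared by several. Of these 113, 12 had a direct neighbour with the identical split, against a median of 0 and a highest of 4 in 10000 random placements (permutation p = 1e-04, the smallest possible). The pairs were Myh2 and Myh1, D730005E14Rik and Apobec3, H2-T23 and H2-T22, Igkv10-94 and Igkv19-93, Trim12a and Trim34b, and Tnnt3 and H19. Myh2 with Myh1 and Tnnt3 with H19 include muscle genes raised in C3H/HeJ replicate 2; without that array 10 of 100 genes had such a neighbour (highest of random placements 2; permutation p = 1e-04). Trim12a and Trim34b moved in opposite directions.

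Random splits of the arrays and strains asked whether chance can be excluded. It can for the strains: of 100 splits of the 27 arrays, counting the real, only 1 was as large for the F test (5840, highest other 57), the median pair (134, 0) and the common genes (83, 0). For the strain lists also only 1 was as large (126, highest other 105), but the median of the other splits was 75, so random groups of arrays alone give many such list calls. For severity, 11 of 36 splits of the strains gave at least the 2 real calls, 18 at least the 1 call among the common genes (highest other 15) and 24 at least the 10 lists (21). The highest other split, C57BL/6J and KK/HlJ against the rest, gave 13 calls, several times the real count and so points to a structure of the samples, whose cause was not tested. The highest other frequency split, with 5 calls, set C57BL/6J, C57L/J and KK/HlJ against the rest. These strains came first in the order of the samples, so the splits cannot tell strain from run order. For frequency the real count over all genes was 0, which all 84 of 84 splits must reach (highest other 5), so the splits say nothing about it; 29 gave at least 1 common call (12) and 36 at least 12 lists (17). For both traits, 55 of 100 splits gave at least 1 call (6), 33 at least 2 common calls (8) and 29 at least 14 lists (25). Chance therefore cannot be excluded for the counts of severity and of both traits, nor for the common calls and lists of frequency.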
